A study of Rattus norvegicus with 6 samples.

How the data were processed

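RNA from the median eminence of rats was sequenced in 6 samples, 3 from control animals and 3 taken 1 day after the surgery that the labels name PEL. The labels do not spell out this abbreviation, and the sample titles do not say whether the controls had a sham operation. Per the labels' protocols, the tissue was frozen, RNA was extracted with Trizol and libraries were made by standard Illumina methods. Reads were aligned with HISAT2 2.0.5 and assigned to genes with featureCounts 1.5.0-p3, per the submitters' processing notes, which also name DESeq2 1.16.1. The genome build, the annotation release, the strand setting and the read filters are not given in the sources used here, so antisense and overlapping genes and near-identical copies may share reads in ways that cannot be separated.

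The deposited table holds raw read counts per gene made by the authors, with no normalization: whole numbers in 6 columns whose names match the sample titles. It has 34510 rows, of which 32883 carry an Ensembl rat gene identifier and 1627 carry a numbered identifier of the form Novel00306, called placeholder rows below, whose origin the labels do not explain. No row was a total or lacked an identifier. The table pairs no identifier with a gene symbol. The reference gene table used here, of the GRCr8 assembly with 47357 rows, has symbols but no Ensembl identifiers, and 0 of the 34510 identifiers matched it. Names were not guessed from identifiers.

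This limits what could be done with the design fixed before the data were examined. The 27 lists of cell type and pathway genes, and the tests of those lists, need symbols and were not run. The rule for naming genes was to take those with the largest rise and the largest fall among genes past the threshold, with a symbol, a mean of at least 5 CPM over the 6 samples and values of the 2 groups that do not overlap. It was applied without the symbol and biotype conditions, to Ensembl rows, and limited to 2 identifiers per direction. The remaining parts of the rule, which list genes by symbol, could not be applied. Chromosomal positions, gene lengths and GC content are not reported here for the same reason.

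Counts were tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Genes were kept by filterByExpr with its minimum count of 10, which left 17125 rows, scaled by TMM and tested with the quasi-likelihood F test (glmQLFit and glmQLFTest), two-sided, all 6 samples in 1 fit with the group as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Positive log2 fold changes are higher after PEL. Standard errors of log2 fold changes are the size of the log2 fold change divided by the square root of F. CPM values are TMM-scaled. Medians of single libraries use log2(CPM + 1), which understates the change of low genes. Figures were drawn with matplotlib 3.10.9.

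The fit was tested on simulated counts before use, in 20 simulations of this comparison that drew counts from the control means, library sizes and gene dispersions, with 200 genes changed in each and 16842 genes run on average. The test called 67.7% of 2-fold rises, 56.5% of 2-fold falls, 94.0% of 4-fold rises and 84.6% of 4-fold falls. Of all simulated calls, 8.55% were unchanged genes, above the nominal rate. The median estimates for simulated log2 changes of 2 and -2 were 1.99 and -2.00.

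Library totals ranged from 13756297 to 17144108 assigned reads. Counting intervals are 95% exact Clopper-Pearson intervals, and cover counting error only, since PCR copies are not independent molecules. Libraries of the same group were compared by a chi-square test over genes with at least 10 reads in the pair. The statistic per degree of freedom was between 4.50 and 24.1, so no 2 libraries of a group were alike within sampling noise and each counted as 1 replicate. The labels do not say that the samples of a group came from separate animals, so p-values measure the spread between these samples, which may in part be technical. No batch or date is given.

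Alternatives fixed before the data were examined were DESeq2 size factors within edgeR, no filter, a stricter filter of 5 CPM in 3 samples, the DESeq2 1.42.0 Wald test, limma-voom, the replicate number as a block, and leaving out each sample. Added after seeing the data were upper-quartile scaling, scaling by library size alone, leaving out the 20 most abundant genes and leaving out the placeholder rows. The removal of the 20 most abundant genes replaced a planned removal of haemoglobin, pituitary hormone and mitochondrial genes, which needs symbols.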

Results

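Gene expression in the rat median eminence, the part of the hypothalamic floor where hypothalamic axons release hormones toward the pituitary, was measured by RNA sequencing in 3 control samples and in 3 samples collected 1 day after PEL surgery. The series title places the comparison in a study of structural repair and of the recovery of body fluid balance after hypothalamic injury. Assigned reads per library were 13756297, 15942604 and 16746441 in controls and 16465414, 16055170 and 17144108 after PEL. Between 21124 and 21558 of the 34510 rows of the count table had at least 1 read in a library. The most abundant gene took between 1.52% and 1.77% of the reads of each library, and the 20 most abundant genes together took between 7.32% and 8.17%. Genes are given by Ensembl identifier, because the identifiers could not be paired with symbols here.

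The 6 libraries separated by group. The first principal component of log2 CPM carried 50.8% of the variance and placed the control libraries between -33.1 and -28.9. The PEL libraries lay at 33.4 for replicate 1, 54.2 for replicate 2 and 6.71 for replicate 3. Correlations of log2 CPM between control libraries were 0.984 to 0.986, across 17125 genes that are not independent replicates. Those between PEL libraries were 0.971 to 0.978, and PEL replicate 3 correlated at 0.976 to 0.977 with the controls. The spread between libraries was thus wider after PEL than in controls, and PEL replicate 3 lay nearest to the control group.

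One day after PEL, 760 genes rose and 170 fell, so that 81.7% of the 930 changed genes were higher. Among the rising genes, 398 were at least 2-fold, 157 at least 4-fold and 39 at least 8-fold higher, with a median rise of 2.10-fold. Falls were smaller: 46 of the falling genes were at least 2-fold, 11 at least 4-fold and 2 at least 8-fold lower, with a median fall of 1.62-fold. In all 930 genes the 3 PEL values lay on one side of the 3 control values. Such separation was found in 30.0% of all tested genes, where chance alone gives 10%. The changed genes were 5.43% of the 17125 tested by edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05, and 3883 genes, 2438 higher and 1445 lower, had an unadjusted p under 0.05. The number differed between tools and depended on single libraries: the DESeq2 Wald test, with its own filter and size factors, called 1635 genes, limma-voom called 651, and the edgeR count was 179 without control replicate 1, 185 without control replicate 2, 229 without control replicate 3, 264 without PEL replicate 1, 684 without PEL replicate 2 and 2107 without PEL replicate 3. With rises still in the majority in each of these fits, their share of the calls ranged from 69.7% without PEL replicate 3 to 93.3% without control replicate 1. Leaving out 1 library gave 134 to 639 genes at least 2-fold higher and 10 to 166 at least 2-fold lower. With the replicate number as a block, 547 genes were called, 96 of them lower.

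**Figure D1:**
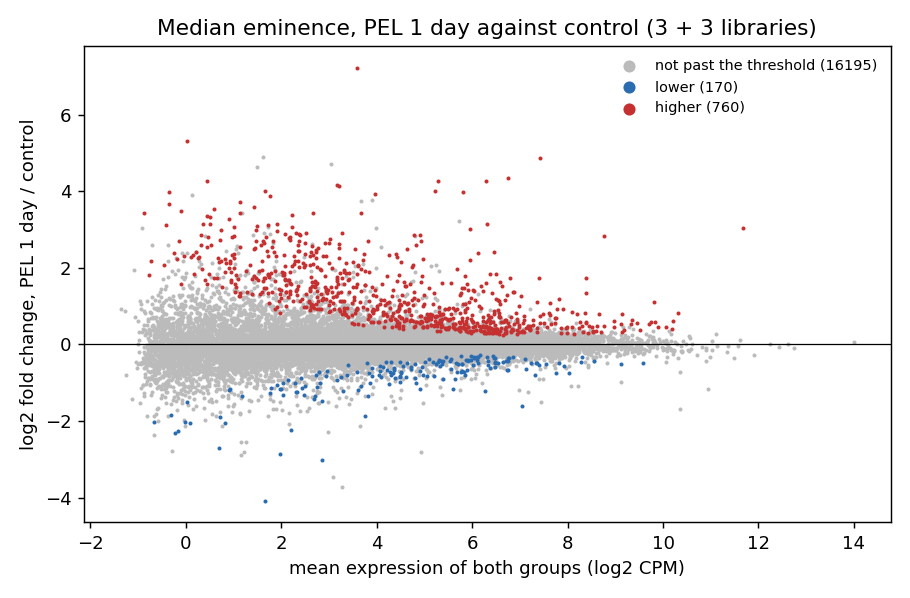
Log2 fold change of PEL 1 day over control (vertical axis) against the log2 of the mean CPM of both groups (horizontal axis) for the 17125 tested genes, each a point, with 3 libraries per group. The 760 genes that rose (red) outnumber the 170 that fell (blue).

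Among called Ensembl genes with a mean of at least 5 CPM, the largest rise was in ENSRNOG00000010478, which went from 0.157 ± 0.119 CPM in controls to 23.8 ± 14.3 CPM after PEL (SD, n = 3 each). Its control level rested on 7 reads over the 3 libraries, against 1162 reads after PEL. The pooled reads gave a 158-fold ratio, with a counting interval of 76.4 to 393, and the fitted log2 fold change was 7.23 (SE 0.64, edgeR adjusted p = 0.00241). The next largest rise was in ENSRNOG00000043451, which was already expressed in controls at 11.4 ± 1.81 CPM and reached 330 ± 202 CPM after PEL (SD, n = 3 each), a log2 fold change of 4.86 (SE 0.47, edgeR adjusted p = 0.00257). Both genes were highest in PEL replicate 2, at 40.2 and 552 CPM, and lowest of the PEL group in replicate 3, at 14.0 and 157 CPM. The largest fall among them was in ENSRNOG00000050407, from 12.9 ± 5.59 to 1.59 ± 0.289 CPM (SD, n = 3 each), a log2 fold change of -3.02 (SE 0.35, edgeR adjusted p = 0.00463). Its control values ranged from 7.73 to 18.8 CPM. ENSRNOG00000019404 fell from 21.1 ± 6.57 to 5.77 ± 1.54 CPM (SD, n = 3 each), a log2 fold change of -1.87 (SE 0.27, edgeR adjusted p = 0.0111).

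**Figure D2:**
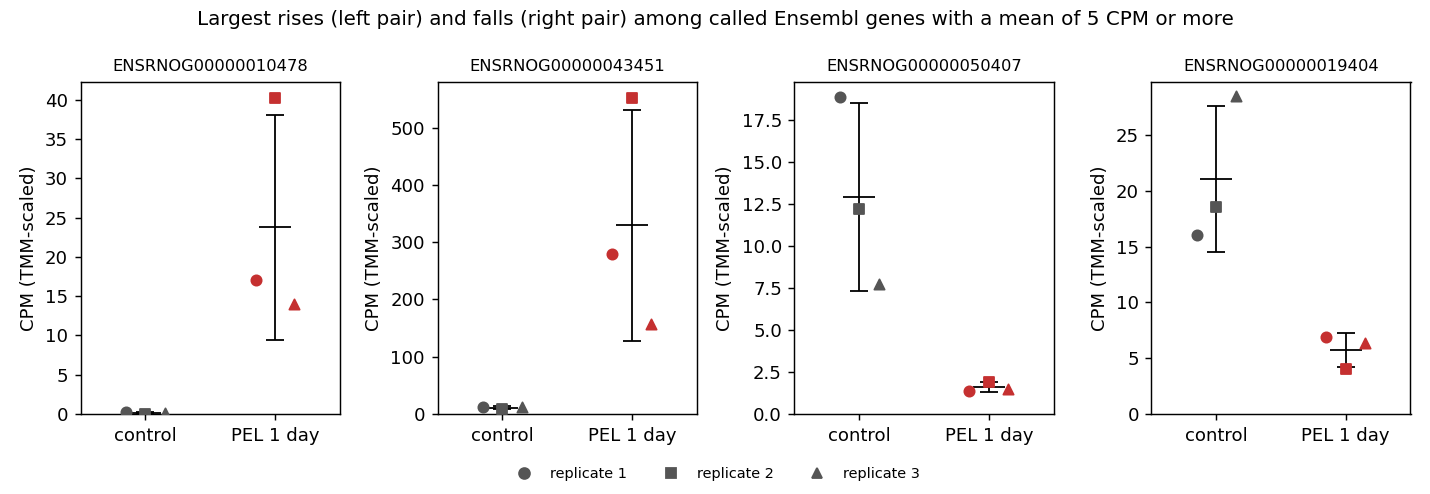
TMM-scaled CPM on linear axes that start at 0 for the called Ensembl genes with a mean of at least 5 CPM and the largest rises (ENSRNOG00000010478 and ENSRNOG00000043451) and the largest falls (ENSRNOG00000050407 and ENSRNOG00000019404). Symbols are single libraries by replicate number, and bars give the mean ± SD of 3 libraries. The groups do not overlap for any of these genes, and the PEL libraries spread widely for both rises, for example between 157 and 552 CPM for ENSRNOG00000043451.

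Rising genes were found from barely expressed to abundant transcripts. With the tested genes divided into 4 classes of equal size by mean CPM over all samples, the lowest class (up to 5.30 CPM) had 173 rising and 27 falling genes, and the highest class (from 57.8 CPM) had 220 rising and 53 falling genes. The classes between them had 197 (5.30 to 21.2 CPM) and 170 (21.2 to 57.7 CPM) rising genes against 44 and 46 falling genes. Rises were larger where expression was low, with a median of 4.21-fold in the lowest class and 1.47-fold in the highest, where smaller changes pass the test. Falls followed the same order, with medians of 2.55-fold in the lowest class and 1.38-fold in the highest. In the class of 21.2 to 57.7 CPM the medians were 1.625-fold for rises and 1.501-fold for falls. Among the rising genes, 88 had a mean under 1 CPM in controls, and 3 of these reached 10 CPM or more after PEL. Another 88 rising genes had a control mean of at least 100 CPM, as did 32 of the falling genes. No called gene lacked reads in every library of 1 group, so the calls include 0 genes detected in 1 group alone.

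The rising genes held 3.98 ± 0.0679% of the reads in controls and 6.90 ± 0.924% after PEL (SD, n = 3 each), and the falling genes held 1.19 ± 0.0171% and 0.792 ± 0.0544%. These sets were chosen on the same libraries, so the shares describe the size of the change and do not test it. The gain was concentrated: 10 genes accounted for 31.2% of the CPM gained by the 760. The gene that gained the most reads went from 0.0713 ± 0.00892% to 0.577 ± 0.113% of all reads in tested genes (SD, n = 3 each), a log2 fold change of 3.04 (SE 0.17, edgeR adjusted p = 0.000656), and became the gene ranked 4 by abundance after PEL. The gene that lost the most reads among the falling genes went from 0.0892 ± 0.00255% to 0.0629 ± 0.00426% (SD, n = 3 each), a log2 fold change of -0.48 (SE 0.08, edgeR adjusted p = 0.0185). These 2 genes were singled out after their values were seen. They were taken from all called rows, placeholder rows included, and their identifiers are not given here.

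**Figure D3:**
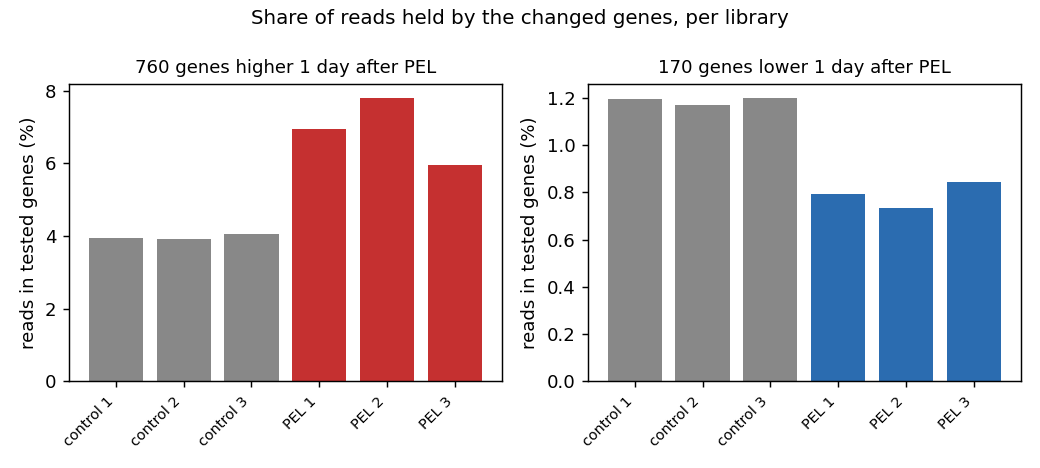
Share of the reads in tested genes (percent, axes from 0) held by the 760 rising genes (left) and the 170 falling genes (right), 1 bar per library, with controls in grey. The rising genes held 3.93% to 4.06% of reads in controls and 6.94%, 7.81% and 5.96% in PEL replicates 1, 2 and 3.

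Both the rising and the falling genes moved furthest in PEL replicate 2 and least in PEL replicate 3. The median log2 change of the rising genes from the control mean was 0.93 in replicate 1, 1.09 in replicate 2 and 0.69 in replicate 3, and that of the falling genes was -0.61, -0.74 and -0.53. PEL replicate 2 was the most changed library for 69.5% of the rising genes and 56.5% of the falling genes, where equal libraries would give 33.3%. PEL replicate 3 was the least changed for 79.5% and 59.4%. Genes called without a given PEL library were then examined in it, limited to those that also passed the filter over all 6 samples. That filter includes the examined library. It left 1440 of 1468 rising genes for replicate 3, 229 of 232 for replicate 1 and 557 of 559 for replicate 2. Of the 1440 genes kept that rose without replicate 3, 97.0% lay above the control mean in replicate 3, with a median log2 change of 0.38. Of the 229 genes kept that rose without replicate 1, 99.1% lay above the control mean in that library, with a median of 1.40. Of the 557 kept that rose without replicate 2, 98.2% lay above the control mean in replicate 2, with a median of 1.25. For falling genes, 85.4% of the 638 kept from 639 lay below the control mean in replicate 3, 90.6% of 32 in replicate 1 and 95.2% of 125 in replicate 2. The medians are not comparable between libraries, because each comes from a different list of genes. Both steps share the control libraries, which raises these shares even with no change in the held-out library: in 20 simulations of an unchanged library in place of each PEL replicate, at most 62.2% of rising genes lay above and at most 70.7% of falling genes lay below the control mean.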

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

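Upper-quartile scaling, library size alone, leaving out the 20 most abundant genes and leaving out the placeholder rows were chosen after seeing the data. The 4 genes given by identifier kept their direction and an edgeR, DESeq2 or limma adjusted p under 0.05 in each of 16 alternatives, with log2 fold changes of 6.61 to 7.91, 4.26 to 5.19, -3.29 to -2.65 and -2.03 to -1.59 and adjusted p no higher than 0.0347, 0.0241, 0.0382 and 0.0461, in the order ENSRNOG00000010478, ENSRNOG00000043451, ENSRNOG00000050407, ENSRNOG00000019404. No gene of the 930 changed sign in any alternative that tested it. For these genes, the 4 included, the values of the 2 groups do not overlap. Leaving out a sample could therefore hardly reverse a direction, and the kept signs are no test of stability. The counts of called genes varied. The DESeq2 Wald test called 1635 genes (1196 higher, 439 lower, 90 at least 2-fold lower) and shared 920 of the 930. It left 6220 adjusted p undefined. The stricter filter left 253 genes at least 2-fold higher and 28 at least 2-fold lower, with 167 of the 930 no longer tested. Leaving out 1 sample gave 179 to 2107 changed genes, 166 to 1468 higher, 12 to 639 lower, 134 to 639 at least 2-fold higher and 10 to 166 at least 2-fold lower. Leaving out any control library, PEL replicate 1 or PEL replicate 2 (684) lowered the count, and leaving out PEL replicate 3 raised it to 2107, with 901 of the 930 among them. The cause was not tested. With the replicate number as a replicate block the count was 547 (451 higher, 96 lower). Same-numbered samples showed no shared deviation, with correlations of 0.002, -0.067 and -0.066. With 3 libraries per group these correlations cannot exclude that the numbers pair the samples. Calls were 901 with DESeq2 size factors, 1095 with no filter, 651 with limma-voom, 896 with upper-quartile scaling, 832 with library size alone, 926 without the 20 most abundant genes and 905 without placeholder rows. Rises made up 75.0% of calls with library size alone, against 81.7% as reported, and 73.2% with DESeq2. The tests of the gene lists and the removal of genes by name were not run, because identifiers could not be paired with symbols. At this depth and with 3 libraries per group, 2-fold falls were called in 56.5% of simulated cases.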

Other observations

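The 1627 rows with placeholder identifiers (of the form Novel00306) behaved differently from the Ensembl rows. They held 1.38 ± 0.0150% of the reads in controls and 1.25 ± 0.0535% after PEL (SD, n = 3 each), with all 3 PEL libraries (1.20%, 1.26% and 1.31%) below all 3 control libraries (1.39%, 1.38% and 1.36%). An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. Of 1319 such rows tested, 14 rose and 14 fell, against 746 and 156 Ensembl rows, and 69.3% had a log2 fold change below 0, against 49.4% of Ensembl rows.

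The tests on the size of the response in single PEL libraries, on upper-quartile and library-size scaling, on abundant genes and on the placeholder rows were chosen after the data had been seen. What was expected of the abundant-gene and placeholder-row tests was written before their own results.

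With the 6 samples split into 3 and 3 in each of the 10 possible ways, the real split gave 930 changed genes and the highest other split gave 1. Only 1 split, the real one, gave as many, but 10 splits are too few for a share under 0.05. Every other split mixes samples of both groups, so a difference between the groups widens its spread and lowers its count. The contrast of these counts therefore decides nothing.

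The first pattern is that rises outnumbered falls by 760 to 170. The choice among the scalings tried is argued against as the whole cause, since rises made up at least 75.0% of calls under 3 other scalings. These differed little from TMM, with a largest median shift in log2 fold change of -0.0232, for library size alone. None of them could show a change shared by most genes, so scaling in that wider sense stays open. Greater power for rises could add to the excess. With as many 2-fold and 4-fold rises as falls put into simulated counts, 53.4% of those detected were rises, against 81.7% in the data. Among called changes of at least 2-fold, 398 were rises and 46 were falls, so power falls short of the excess there. Changes under 2-fold were not simulated, so for them the part played by power stays open. Leaving out the 20 most abundant genes gave 81.75% but moved almost no call, so it tests nothing. What also stays open, untested, is the surgery itself as the difference between the groups, and a change in the cells present could not be examined without marker genes.

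The second pattern is the order of the PEL libraries, with replicate 2 most and replicate 3 least changed. Genes were here called from PEL replicate 1 against the 3 controls, where the controls alone give the spread. Their changes from the control mean were taken in CPM, not in log2. The median change in replicate 3 was 0.473 of that in replicate 2 over the rising genes (95% bootstrap interval over genes, which are not independent, 0.431 to 0.515). Over the falling genes it was 0.367 of that in replicate 2 (0.312 to 0.420). With all libraries thinned to 13756297 reads the ratio of rising genes was 0.463 (0.423 to 0.498). The changes are in CPM, already divided by library size, so thinning could hardly move their ratio and decides little about library size. Replicate 3, the least changed, had 17144108 reads, against 16055170 in replicate 2. Unaffected tissue mixed into replicate 3 may be part of the cause and stays open. The intervals of the ratios of rising and falling genes lay apart as deposited. They overlapped after a single random thinning, with 0.369 (0.311 to 0.437) for falling genes. Such overlap does not show that the ratios are equal. Medians of single-gene ratios, over genes moving the same way in replicate 2, overlapped as deposited (0.439 to 0.482 for rising genes, 0.367 to 0.459 for falling genes). A milder response in replicate 3 allows the same values. As the whole cause, unaffected tissue would give every gene the same ratio. Of 171 genes called at least 4-fold higher from replicate 1, 157 lay above the controls in both other PEL libraries. These had a spread of the log2 ratio (MAD) of 0.890 (0.738 to 1.18), against at most 0.383 between control libraries. The interval reaches below a bound of 2 times the control value, which was set after the data were seen. The 2 spreads are also unlike measures, since 0.5 was added to CPM for the controls only. Unaffected tissue as the whole cause therefore stays open too.

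The third pattern is the lower level of the placeholder rows. Their median log2 fold change was -0.155, against 0.0047 for Ensembl rows, and lay between -0.199 and -0.122 when each library was left out and between -0.177 and -0.164 under 3 other scalings. Low counts are argued against as the cause, since the medians of 1000 draws of Ensembl rows matched on mean log2 CPM lay between -0.0546 and 0.0285. The draws treat rows as independent. The estimated correlation between placeholder rows was 0.0195, and the median of correlated rows can vary more widely than this range. Reads taken up by the called rising genes are argued against as the whole cause. Outside the called genes, the highest PEL share was 1.352% and the lowest control share was 1.378%. Rises that were not called stayed in this measure, so reads taken up by rising genes remain open as part of the cause. Against all other genes, camera gave p = 3.18e-05 with a preset correlation and p = 0.0386 with an estimated correlation. Beyond the form of the identifier, what these rows are is not stated, so no biological explanation was tested.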
